A study of Homo sapiens with 2 samples.

How the data were processed

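RNA-seq libraries of H9 cells, an established human embryonic stem cell line, were compared between 2 conditions. The cells of one condition had been treated with small interfering RNA against HNRNPA1, the gene of the splicing regulator hnRNP A1, and those of the other with a control small interfering RNA. The treatment lasted 48 h. Per the labels' protocols, total RNA was purified with a column kit and messenger RNA libraries were prepared for Illumina sequencing. Each condition had 1 library that the labels tie to a column of the deposited table, so the comparison has no estimate of the spread between replicates. The table held 6 further columns of per-sample values that match neither library. They were not analysed here.

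The deposited table lists 95139 transcripts of 20263 genes with Ensembl identifiers, gene names, Gene Ontology identifiers and KEGG pathway names. Per the file headers, it gives for each library a count, a TPM and an FPKM per transcript. The counts deposited by the authors are whole numbers, but overlapping transcripts of a gene each carry counts. Of the counts from 1 to 3, 90.2% in each library equalled the value implied by FPKM and transcript length rounded up (tolerance 0.05), so the deposited values were treated as estimated counts that the authors had rounded up. The TPM values deposited by the authors sum to 1000000 per library within rounding. The FPKM values deposited by the authors sum to 520633 in the siHNRNPA1 library and 468831 in the control library. The aligner, the quantification program and the annotation release are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The table itself holds human identifiers: 95033 of its transcripts are in GENCODE release 29 (GRCh38), and 93355 of them have the same position there. Coordinates below are those of the table, on GRCh38. Of the genes, 19722 are protein-coding in that annotation. The long noncoding RNA ESRG, named in the title of the series, was not analysed here.

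The total estimated count was 28147828 for the siHNRNPA1 library and 26680342 for the control library. Intervals on counts are exact (Poisson for a level, Clopper-Pearson for a share, 95%) and treat each estimated count as 1 independent read. They cover counting error only, and neither the spread between samples nor errors in dividing reads between transcripts.

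A gene's FPKM was the sum over its transcripts. Folds are log2((siHNRNPA1 + 1)/(control + 1)) of FPKM, so the fold of a weakly expressed gene is understated. Genes with a mean FPKM of at least 1 were kept, and a gene was counted as higher or lower from 2-fold on. No significance test was applied and no p-value is given, because genes are not replicates. For each of 32 gene lists, the median fold was placed among the medians of 10000 random lists of the same size, drawn with replacement from the same twentieths of mean expression. A list with at least 5 measured members was counted as outside the random range under the 2.5th or over the 97.5th percentile. Such a percentile describes these 2 libraries only. KEGG and Gene Ontology terms with 15 to 300 measured genes were treated in the same way and named only when beyond all 10000 random lists, with at most 5 names per direction. Gene Ontology terms, given by identifier only, were counted. The KEGG pathways p53 signaling, cell cycle and oocyte meiosis were added beside the fixed lists after their values had been seen.

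Transcript shares are a transcript's percentage of the gene's FPKM. They were compared for genes with at least 2 transcripts and at least 5 FPKM in both libraries, and a difference of 20 percentage points was counted. TCF3 transcripts were assigned to the E12 or E47 form by translating their GENCODE sequences in all forward frames and searching the basic helix-loop-helix peptide of each form.

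GC content and length were taken from the GENCODE sequence of each gene's most abundant transcript, which was found for 11916 of the 11921 genes kept. Because folds went with both properties, each gene was also set against its 100 nearest genes in mean expression, GC content and length, by subtracting their median fold and by drawing 10000 random lists from these neighbours. This matching was chosen after the data had been seen.

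The gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. The rule took HNRNPA1, TCF3, ESRG and CDH1, the 12 lowest and 12 highest folds among genes with at least 5 FPKM in either library (leaving out pseudogenes and clone-based names), and the 4 members of each described list with the largest absolute fold. It added POU5F1, SOX2 and NANOG, the 10 genes with the largest transcript share difference among those with at least 10 FPKM in both libraries, and the 4 such genes among literature HNRNPA1 splicing targets. The other hnRNP A/B genes were given beside HNRNPA1. Some genes that the rule takes are not reported here.

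The other settings tried were pseudocounts of 0.1 and 5 FPKM, rescaling to a sum of 1000000 or by the median ratio, the leading transcript in place of the sum, counts scaled to the library total, other expression minimums, a 1.5-fold threshold, the mean of a list, and other minimums and thresholds for transcript shares. On simulated counts for the siHNRNPA1 against control comparison, drawn for the table's genes, 11965 genes passed the expression minimum. Of 96 genes changed by 4-fold, 96.9% were counted as past 2-fold. So was 1 of 11772 unchanged genes, and none of 97 genes changed by less than 2-fold. These counts held counting error only. They had no spread between samples, no trend with GC content or length and no error in dividing reads between transcripts. They therefore give no rate of false calls for the real libraries. Of 20 simulated lists of long transcripts under a pure GC and length trend, 18 left the range of expression-matched lists and 1 left that of the lists matched on GC content and length as well. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.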

Results

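The series concerns how alternative splicing of TCF3 bears on self-renewal of human embryonic stem cells. The data analysed here are transcript-level RNA-seq values of H9 cells 48 h after the start of treatment with small interfering RNA against HNRNPA1 or with a control small interfering RNA, with 1 library per condition. Depth was similar, at 28147828 estimated counts in the siHNRNPA1 library and 26680342 in the control library. The number of transcripts with a count above 0 was 51689 in the siHNRNPA1 library and 56438 in the control library. Transcripts of the 13 mitochondrial protein-coding genes made up 18.1% of TPM in the siHNRNPA1 library and 28.2% in the control library. No difference below has a replicate check.

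HNRNPA1 itself was measured first, since its level bears on the labels. The gene (ENSG00000135486, chromosome 12, 54280193 to 54287088, plus strand) had 179.9 FPKM in the siHNRNPA1 library (95% counting interval 177 to 183) and 663 FPKM in the control library (657 to 668). The siHNRNPA1 library thus held 27.1% of the control level, a log2 fold of -1.88. Of the genes kept, 4.31% had a lower fold than HNRNPA1. Its near relatives share sequence with it. HNRNPA2B1 had a log2 fold of 0.04, HNRNPA3 of -0.11, HNRNPA1L2 of -0.50, HNRNPA0 of 0.63 and HNRNPAB of 0.99. The median fold of the 100 genes nearest to HNRNPA1 in expression, GC content and length was close to 0, and after its subtraction HNRNPA1 stood at -1.87. By the same measure HNRNPA0 stood at 1.96, HNRNPA3 at 0.92, HNRNPAB at 0.50, HNRNPA2B1 at -0.18 and HNRNPA1L2 at -0.44.

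Across the transcriptome, more genes were lower than higher in the siHNRNPA1 library. Of 11921 genes with a mean FPKM of at least 1, 2609 were at least 2-fold lower and 1480 at least 2-fold higher, so that 36.2% of the genes past 2-fold were higher. With the libraries rescaled by their median ratio, 46.6% were higher (1906 against 2184). With a pseudocount of 5 FPKM 841 were higher and 947 lower. The median log2 fold of all genes was -0.13 as deposited, -0.30 after rescaling to a sum of 1000000 and 0.0046 after median ratio scaling. Folds went with base composition and length of the transcripts. Across genes, which are not independent replicates, Spearman's rho with the fold was 0.58 for GC content and -0.46 for length. With the genes in 5 equal groups by GC content, 48.7% of the group with the lowest content were at least 2-fold lower and 1.30% at least 2-fold higher. The corresponding values in the group with the highest content were 2.01% and 28.3%. The 2-fold lower genes had a median GC content of 42.8% and the 2-fold higher genes one of 59.1%. After subtraction of the median fold of each gene's 100 nearest genes in expression, GC content and length, 67.7% of the genes past 2-fold were within 2-fold. By that measure 1003 genes were at least 2-fold lower and 962 at least 2-fold higher, a share of 49.0% higher.

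**Figure D1:**
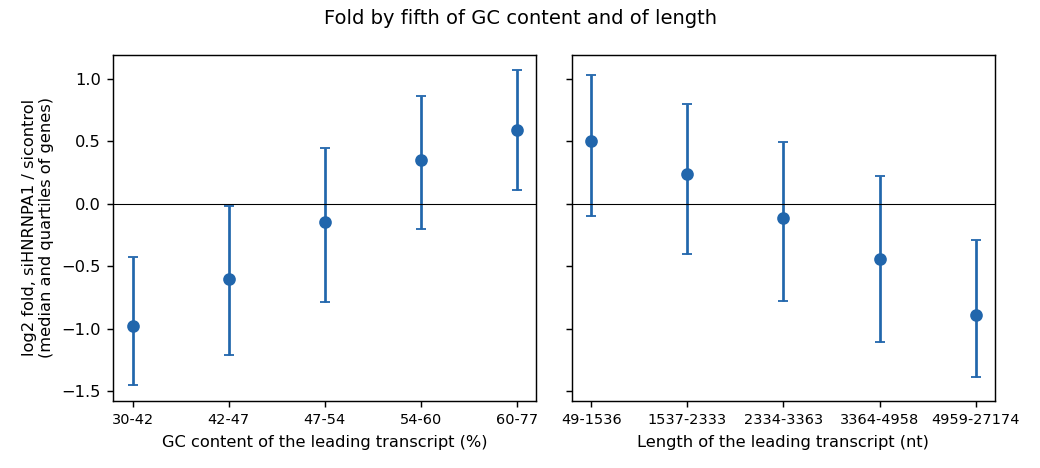
Median log2 fold (siHNRNPA1 over control, FPKM + 1) of genes in 5 equal groups by GC content (left, in %) and by length (right, in nucleotides) of their leading transcript. Points are medians over genes and bars span the quartiles. The median is -0.98 at the lowest GC content and 0.59 at the highest, and 0.50 for the shortest transcripts and -0.89 for the longest.

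The 12 genes with the lowest folds had log2 folds from -4.36 to -3.29. SULF1, a heparan sulfate endosulfatase, had 0.560 FPKM in the siHNRNPA1 library and 23.9 in the control (log2 fold -4.00). ROBO1, the axon guidance receptor, had 2.04 and 33.9 FPKM (-3.52), and FAT1, an atypical cadherin, 1.64 and 25.2 FPKM (-3.31). AFDN, the adherens junction scaffold afadin, stood at -3.39 and API5, an apoptosis inhibitor, at -3.37. Among RNA-binding proteins PTBP3 had 0.187 and 14.2 FPKM (-3.68) and PUM2, a Pumilio repressor, 0.462 and 14.3 FPKM (-3.39). PRR11, which overlaps another gene on the same strand, had a log2 fold of -3.71, MAN2A1, a Golgi mannosidase, of -3.41, and SLC4A7, a bicarbonate cotransporter, of -3.29. ZBED6, at -3.31, overlaps ZC3H11A on the same strand, so its reads cannot be assigned with certainty. MATR3, a nuclear matrix protein, has 2 overlapping entries. The entry ENSG00000280987 was among these genes at -4.36, while both entries together had 36.0 FPKM in the siHNRNPA1 library and 156 in the control (-2.08). All 12 stayed at least 2-fold below their nearest genes in expression, GC content and length. For AFDN, SULF1 and FAT1 the length used was that of a short leading transcript, of 606, 630 and 1305 nucleotides. They were thus set against genes with short transcripts, whose folds were higher, and stood at -4.14, -4.13 and -3.94 after the subtraction. The estimated counts of SULF1 (99 in the siHNRNPA1 library and 2016 in the control) and FAT1 (762 and 5245) differed relatively less than their FPKM. Those of the MATR3 entry ENSG00000280987 (144 and 9433) differed relatively more.

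At the other end were the 12 genes with the highest folds. DDIT3, the stress transcription factor CHOP, had 30.2 FPKM in the siHNRNPA1 library and 1.55 in the control (log2 fold 3.62). HMOX1, heme oxygenase 1, had 109 and 8.66 FPKM (3.51). CLDN6, a tight junction claudin of pluripotent cells, had 337 and 36.7 FPKM (3.16), and the secreted VGF precursor 119 and 12.4 FPKM (3.16). PKDCC, a secreted kinase, stood at 3.20. SPIB, an ETS factor, had 15.5 and 0.889 FPKM (3.13) and LBHD1 24.7 and 1.32 FPKM (3.47), and both overlap another gene on the same strand. The estimated counts of SPIB, 899 in the siHNRNPA1 library and 89 in the control, differed relatively less than its FPKM. Among the 12 were also 4 readthrough genes whose reads are shared with their component genes. SENP3-EIF4A1 had 15.9 and 0.584 FPKM. RTEL1-TNFRSF6B, NEDD8-MDP1 and JMJD7-PLA2G4B were listed at 0 in the control library. Against a floor of 3 counts in that library their share of counts was 391-fold, 50.6-fold and 230-fold higher. The floor allows for counting error only. These ratios are therefore not lower bounds, because a listed 0 may come from how the shared reads were divided. All 12 stayed at least 2-fold above their nearest genes. The counting interval of the log2 ratio reached a half-width of at most 0.44 for those of these 24 genes, HNRNPA1, TCF3 and CDH1 that had counts in both libraries.

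Genes of the hnRNP family were lower as a group. Of 32 measured hnRNP family genes other than HNRNPA1, 6 were at least 2-fold lower and none higher, or 5 and 1 after the subtraction. Their median log2 fold of -0.39 lay below all 10000 expression-matched random lists, and at the 1.24th percentile of lists matched on GC content and length as well. PTBP3 (-3.68), PTBP2 (-2.61), TARDBP (-2.11) and HNRNPR (-1.34) had the lowest folds, and TARDBP overlaps another gene on the same strand. The estimated counts of TARDBP, 712 in the siHNRNPA1 library and 1719 in the control, differed relatively less than its FPKM. Among 23 SR proteins and their kinases 7 were at least 2-fold lower and 2 higher, with a median of -0.45 (0.37th percentile). SRSF11 (-2.63), SRRM1 (-2.35), SON (-2.16) and SRPK2 (-1.88) had the largest folds. With GC content and length matched, the SR list lay at the 63.9th percentile, inside the random range. After subtraction of the nearest genes 3 members were at least 2-fold lower and 3 higher, and SRPK2 stood at -0.71. The 3 higher ones, named after their values were seen, were SRSF6 (2.30), SRSF7 (1.80) and SRSF3 (1.79).

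Core pluripotency genes were higher in some cases and lower in others. POU5F1, which encodes OCT4, had 1355 FPKM in the siHNRNPA1 library and 864 in the control (log2 fold 0.65), SOX2 58.3 and 126 FPKM (-1.10), and NANOG 18.0 and 22.6 FPKM (-0.31). After subtraction of the median of the nearest genes POU5F1 stood at -0.10, SOX2 at -1.26 and NANOG at 0.81, so that the signs of POU5F1 and NANOG turned. LIN28B (-1.63) and PODXL (-1.61) were lower and PRDM14 was higher (1.64). Of the 20 genes of the list, 8 were at least 2-fold lower and 2 higher. The list median of -0.57 lay at the 0.04th percentile of expression-matched lists and at the 14.9th once GC content and length were matched, inside the random range, with 5 genes at least 2-fold lower and 2 higher after the subtraction. In the primed pluripotency list 6 of 17 genes were at least 2-fold lower and 1 higher (median -0.36, 3.96th percentile, 17.4th with GC content and length matched). FAT3 (-2.56), DUSP6 (-2.39) and NLGN4X (-1.98) were among its lower members. Only 3 of the naive pluripotency genes were measured. TFAP2C stood at -1.32, SUSD2 at -0.09 and KLF4 at 0.52. Of 11 listed pluripotency long noncoding RNAs TUNAR (-0.54) was the only one in the deposited table, so the levels of the others are unknown. Genes of NODAL and FGF signalling were on both sides, with 5 of 19 at least 2-fold lower and 5 higher, or 1 lower and 3 higher after the subtraction. Their median was -0.09 (40.4th percentile) and their mean 0.02. The NODAL antagonists LEFTY1 (2.88) and LEFTY2 (1.78) were higher, while the ERK phosphatase DUSP6 (-2.39) and the SMAD corepressor SKIL (-2.18) were lower. LEFTY1 overlaps another gene on the same strand. None of 6 measured WNT target genes passed 2-fold at a pseudocount of 1 FPKM (median -0.53, 40.3rd percentile), with MYC at -0.95, AXIN2 at -0.92, ZNRF3 at -0.70 and BMP4 at 0.48. AXIN2 overlaps another gene on the same strand. After the subtraction MYC was at least 2-fold lower (-1.54), but it was matched on a leading transcript of only 577 nucleotides. Its estimated counts were 144 in the siHNRNPA1 library and 196 in the control, a smaller relative difference than in FPKM. LIN28B, NLGN4X and SKIL were then within 2-fold.

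Of the markers of other lineages few passed the expression minimum. Among 8 measured neural ectoderm genes TUBB3 (2.01), NES (1.17) and SIX6 (1.01) were at least 2-fold higher and none was lower at a pseudocount of 1 FPKM. TUBB3 overlaps another gene on the same strand. ZIC1 stood at -0.97, with 1.14 FPKM in the siHNRNPA1 library and 3.18 in the control, and at -0.21 after subtraction of the nearest genes. The list had a median of -0.22, a mean of 0.24 and the 39.1st percentile. After the subtraction 1 of the 8 genes was at least 2-fold lower and 1 higher. The neural crest list had 2 of 7 genes at least 2-fold lower, ETS1 (-1.42) and SOX9 (-1.25), with PAX7 at -0.76 and FOXD3 at 0.46. Its median was -0.20, at the 63.1st percentile (27.2nd with GC content and length matched). None of its genes was past 2-fold after the subtraction, with ETS1 at -0.33 and SOX9 at -0.68. Of the mesoderm list 4 genes were measured, with KDR at -1.87, NKX2-5 at 0.54, BMP4 at 0.48 and TBX6 at -0.42 (median 0.03, mean -0.32). The definitive endoderm list had CER1 (0.56) alone. The trophoblast and amnion list lay above the random range (median 0.86 over 6 genes, 99.0th percentile). Of its epithelial keratins KRT18 (1.60) was at least 2-fold higher and KRT8 stood at 0.98, within 2-fold. GABRP (-1.50) and TFAP2C (-1.32) were lower. With GC content and length matched it lay at the 96.2nd percentile, inside the random range. Fibroblast markers had 4 of 12 genes at least 2-fold lower and 1 higher (median -0.41, 7.48th percentile, 2.15th with GC content and length matched). They included FN1 (-2.89), COL6A3 (-1.55), MMP2 (-1.46) and VIM (-1.12). NES, SIX6, KDR and KRT18 were also within 2-fold after the subtraction.

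Genes of epithelial adhesion were lower as a group. CDH1, which encodes E-cadherin (chromosome 16, 68737225 to 68835548), had 15.9 FPKM in the siHNRNPA1 library and 46.9 in the control (log2 fold -1.50, or -0.84 after subtraction of the median of its nearest genes). Its estimated counts were 2588 and 5117, a smaller relative difference than in FPKM. Of 20 epithelial adhesion genes 7 were at least 2-fold lower and 1 higher. The median of -0.64 lay at the 0.91st percentile of expression-matched lists and at the 0.13th with GC content and length matched. The desmosomal genes DSP (-2.52) and DSG2 (-2.28) and the epithelial splicing regulator ESRP1 (-2.13) were lower, and CLDN6 (3.16) was the only member at least 2-fold higher. Of 14 measured mesenchymal genes, 5 were at least 2-fold lower and 1 higher, with a median of -0.54 (5.79th percentile, 0.56th with GC content and length matched). FN1 (-2.89), CDH2, which encodes N-cadherin (-1.63), MMP2 (-1.46) and SPARC (-1.20) had the largest folds. In the list of E-proteins, their inhibitors and related genes 3 of 9 genes were at least 2-fold higher and 4 lower. These counts include the cell cycle inhibitors CDKN1A (1.24) and CDKN1C (-1.32), which belong to neither family. The E-protein inhibitors ID3 (1.98) and ID1 (1.75) were higher, but ID2 was lower (-1.39), as were the E-protein genes TCF12 (-1.94) and TCF4 (-1.70). The list had a median of -0.17, at the 31.4th percentile. After subtraction of the nearest genes TCF12 (-0.64) and TCF4 (-0.26) were within 2-fold, while ID2 stood at -1.36. ID2, CDKN1A and CDKN1C were named after their values were seen. CDH2 and SPARC were also within 2-fold by that measure.

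The genes of the mitosis list were lower as a group, and those of the p53 target list were higher. Of 26 mitosis genes 18 were at least 2-fold lower and none was 2-fold higher. TOP2A, the topoisomerase of dividing cells, had 11.9 FPKM in the siHNRNPA1 library and 81.0 in the control (log2 fold -2.66). BUB1 (-2.41), BUB1B (-2.29) and MKI67 (-2.24) followed. BUB1B overlaps the readthrough gene BUB1B-PAK6 on the same strand. Above 0, and named after their values were seen, were CCNB1 (0.55), CDC20 (0.42), UBE2C (0.32), AURKB (0.29) and AURKA (0.14). CCNB1 stood at 1.09 after subtraction of the median of its nearest genes. The list median of -1.28 lay below all 10000 expression-matched lists and at the 0.06th percentile with GC content and length matched, where the median after subtraction of the nearest genes was -0.59, with 7 genes at least 2-fold lower and 1 higher. Genes of the G1/S transition and replication were inside the random range (median 0.18, 41.0th percentile, 5 of 26 at least 2-fold higher and 1 lower, or 3 and 1 after the subtraction). CCNA2 (-1.71) was lower, while E2F1 (43.2 and 14.7 FPKM), GINS2 (1.37) and MCM5 (1.31) were higher. Of these, GINS2 alone was past 2-fold after the subtraction, with CCNA2 at -0.82, E2F1 at 0.87 and MCM5 at 0.72. Among 18 p53 targets 9 were at least 2-fold higher and 1 lower, with a median of 1.02 above all 10000 expression-matched lists and all 10000 lists matched on GC content and length as well. After the subtraction 5 were at least 2-fold higher and none lower. The pro-apoptotic gene BAX had 148 and 40.2 FPKM (1.86), TP53I3 stood at 1.51 and GDF15 at 1.60 with only 12 counts in the control library. RRM2B (-2.15) was lower. After that subtraction BAX stood at 0.85, TP53I3 at 0.88 and RRM2B at -0.88, all within 2-fold, and GDF15 at 1.21. The KEGG p53 signaling pathway was not higher, with a median of -0.21 over 56 measured genes. Of these, 14 were at least 2-fold lower and 7 higher. It lay inside the random range (25.7th percentile, 60.35th with GC content and length matched). In the integrated stress response list 8 of 22 genes were at least 2-fold higher and 1 lower. DDIT3 (3.62), TRIB3 (2.39), DDIT4 (1.96) and SLC3A2 (1.71) led it, but the median of 0.38 lay at the 76.5th percentile, inside the random range, and 5 genes were at least 2-fold higher and none lower after the subtraction. Interferon response genes, a readout of double-stranded RNA, had a median of -0.08 and a mean of 0.05 (56.8th percentile), with IRF1 at 1.39, ISG15 at 1.10 and IRF7 at 0.93. After subtraction of the nearest genes ISG15 stood at -0.040.

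Histone genes were higher and cholesterol synthesis genes lower as groups, while the call for the list of cytosolic ribosomal proteins was lost with GC content and length matched. Of 35 cytosolic ribosomal protein genes 11 were at least 2-fold higher and none lower (median 0.86, 99.6th percentile). RPS12 (1.87), RPS14 (1.83), RPS19 (1.73) and RPLP1 (1.60) led. With GC content and length matched the list lay at the 96.4th percentile, inside the random range. Its median after subtraction of the nearest genes was 0.14, with 4 genes at least 2-fold higher. Of 27 listed replication-dependent histone genes 14 were in the deposited table and 7 were measured. Among these 7 genes 6 were at least 2-fold higher (median 1.76, above all 10000 random lists and at the 99.98th percentile with GC content and length matched). HIST1H2BD (2.72), HIST1H1C (2.46), HIST1H2BK (1.80) and HIST1H2BJ (1.76) had low levels, with 6 to 129 counts in the control library, and histone genes share sequence with close copies. After the subtraction 4 of the 7 genes were at least 2-fold higher. For HIST1H2BJ the counting interval of the log2 ratio had a half-width of 1.33. Whether histone messages were captured alike in both messenger RNA libraries was not tested. Cholesterol synthesis genes had 8 of 24 members at least 2-fold lower and 1 higher (median -0.43, 0.17th percentile, 1.02nd with GC content and length matched, with 4 lower and none higher after the subtraction). SC5D (-2.19), HMGCS1 (-1.88) and SQLE (-1.66) were lower and PMVK (1.71) was higher. The lists that follow lay inside the random range. Oxidative phosphorylation (median 0.58, 81.2nd percentile) had 9 of 28 genes at least 2-fold higher, or 4 after the subtraction, among the 9 UQCRQ (1.89), NDUFS3 (1.82), NDUFA2 (1.59) and NDUFA1 (1.38). Glycolysis (0.23, 23.6th percentile) had PDK1 (-1.79) and HK2 (-1.06) lower and SLC2A1 (1.26) and ENO1 (1.19) higher. Hypoxia targets (-0.37, 34.0th percentile) had MXI1 (-2.47), P4HA1 (-1.85) and PDK1 lower and ADM (2.15) higher. Polycomb and DNA methylation genes had 6 of 13 members at least 2-fold lower, led by TET1 (-1.89), SUZ12 (-1.62), RNF2 (-1.25) and JARID2 (-1.20), with a median of -0.06 (51.6th percentile, 93.9th with GC content and length matched). After subtraction of the nearest genes none was 2-fold lower and 1 was higher, and these 4 genes stood at -0.45, -0.53, -0.15 and -0.70. Of 20 listed genes sensitive to nonsense-mediated decay 12 were in the deposited table. Of these 12 genes 2 were at least 2-fold lower, among them SMG1 (-1.80), and 1 was higher, SMG5 (1.03). UPF2 stood at -0.78, and the list had a median of -0.0022 and the 51.6th percentile. After the subtraction 1 was at least 2-fold lower and none higher. No telomere gene passed 2-fold at a pseudocount of 1 FPKM. POT1 stood at -0.98, NOP10 at 0.81, TERF2IP at -0.81 and TERF1 at -0.78, with a median of 0.04 and a mean of -0.06 (40.3rd percentile). POT1 had 2.16 FPKM in the siHNRNPA1 library and 5.21 in the control. Its estimated counts, 108 and 509, differed relatively more than its FPKM. After the subtraction POT1 stood at 0.01. HMGCS1, PMVK, HIST1H2BK, NDUFA2, NDUFA1, HK2, ENO1, P4HA1, SMG1 and SMG5 were also within 2-fold after the subtraction. In all, 7 of 28 lists with enough measured members lay below the random range and 4 above it, and 7 of these 11 stayed outside on the same side with GC content and length matched.

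**Figure D2:**
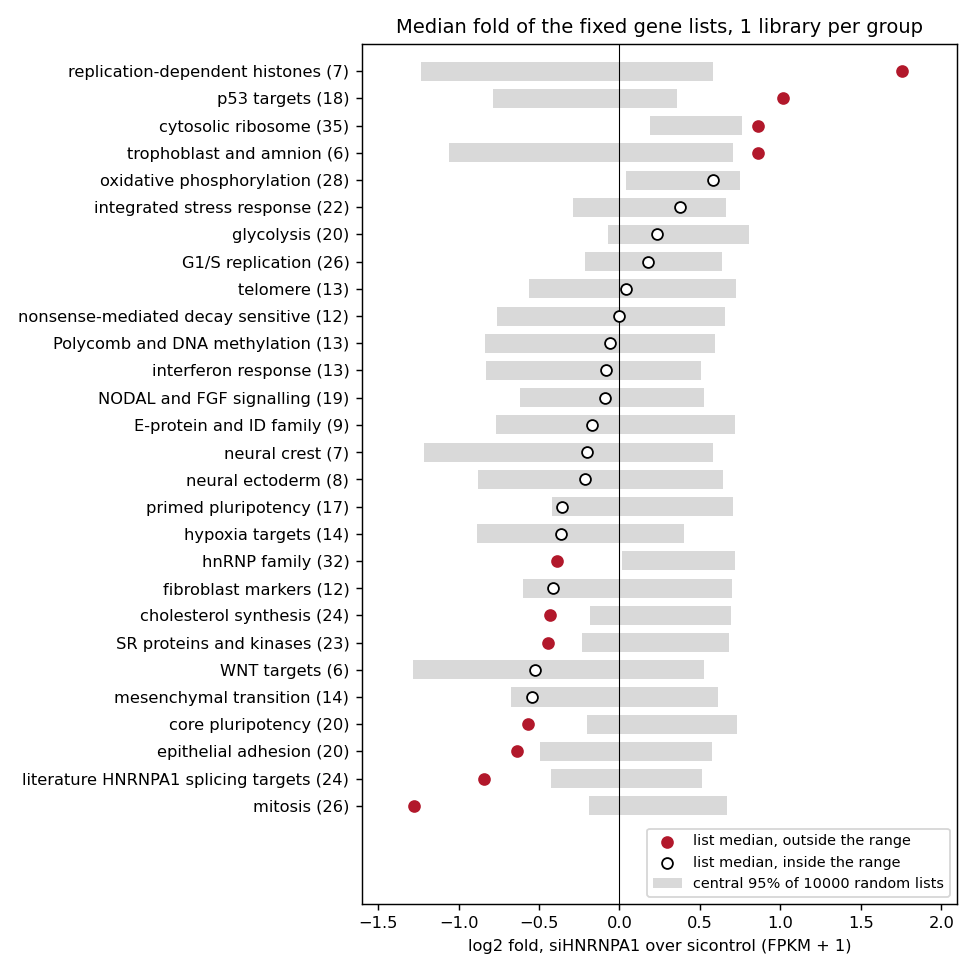
Median log2 fold (siHNRNPA1 over control, FPKM + 1) of each fixed gene list, with the number of measured members in brackets and 1 library per group. Grey bars span the central 95% of 10000 expression-matched random lists, filled points lie outside it and open points inside. The mitosis list has the lowest median (-1.28) and the histone list the highest (1.76).

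Of 264 KEGG pathways, 12 had a median fold below all 10000 random lists and 2 above all of them. The lowest were adherens junction (median log2 fold -0.96, 27 of 61 genes at least 2-fold lower and 1 higher), FoxO signaling (-0.89, 45 of 95 lower), the fly version of MAPK signaling (-0.86), ErbB signaling (-0.79) and EGFR inhibitor resistance (-0.79). The higher ones were ribosome (0.86, 50 of 125 genes at least 2-fold higher) and systemic lupus erythematosus (1.02). The latter is a term whose 55 measured genes include 29 histone genes. When GC content and length were matched as well, 4 of the 12 lower pathways, adherens junction and ErbB signaling among them, and both higher pathways remained beyond all random lists. Of 1828 Gene Ontology terms 38 lay below and 12 above all random lists, against 9 and 9 with that matching. Only 4 terms lay below and 6 above all random lists in both.

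TCF3, the gene in the title of the series, had close total levels in the 2 libraries. It encodes the E-proteins E12 and E47, which differ in a mutually exclusive exon of the basic helix-loop-helix domain. The gene (chromosome 19, 1609290 to 1652605, minus strand) had 69.3 FPKM in the siHNRNPA1 library and 68.8 in the control (log2 fold 0.01). The sign of this fold turned with the scaling. It was -0.14 after rescaling to a sum of 1000000, 0.17 after median ratio scaling, -0.67 from the leading transcript and -0.68 after subtraction of the median of the nearest genes. The E12 exon lies at 1615285 to 1615520 (5 of 7 E12 transcripts) and the E47 exon at 1612207 to 1612433 (4 of 6 E47 transcripts). E47 transcripts summed to 26.4 FPKM in the siHNRNPA1 library and 34.6 in the control, and E12 transcripts to 37.6 and 31.1. Part of the E12 sum comes from transcripts annotated only from within the gene, beginning at 1619209 or further downstream. Among them ENST00000593064 had 5.25 FPKM in the siHNRNPA1 library and 2.38 in the control. The values were 5.93 and 1.92 for ENST00000592628, 5.45 and 2.84 for ENST00000586164, and 2.66 and 2.61 for ENST00000587425. The E47 share of E12 plus E47 was 41.3% in the siHNRNPA1 library and 52.6% in the control, a difference of -11.4 percentage points. By estimated counts the share was 44.2% (95% Clopper-Pearson interval 42.9 to 45.4) and 52.4% (51.2 to 53.6). These intervals do not overlap, but they cover counting error only. Transcripts of the same form differed in opposite directions. The E12 transcript ENST00000262965 made up 3.24% of the gene in the siHNRNPA1 library and 26.0% in the control, while the E12 transcript ENST00000611869 made up 19.4% and 3.63%.

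**Figure D3:**
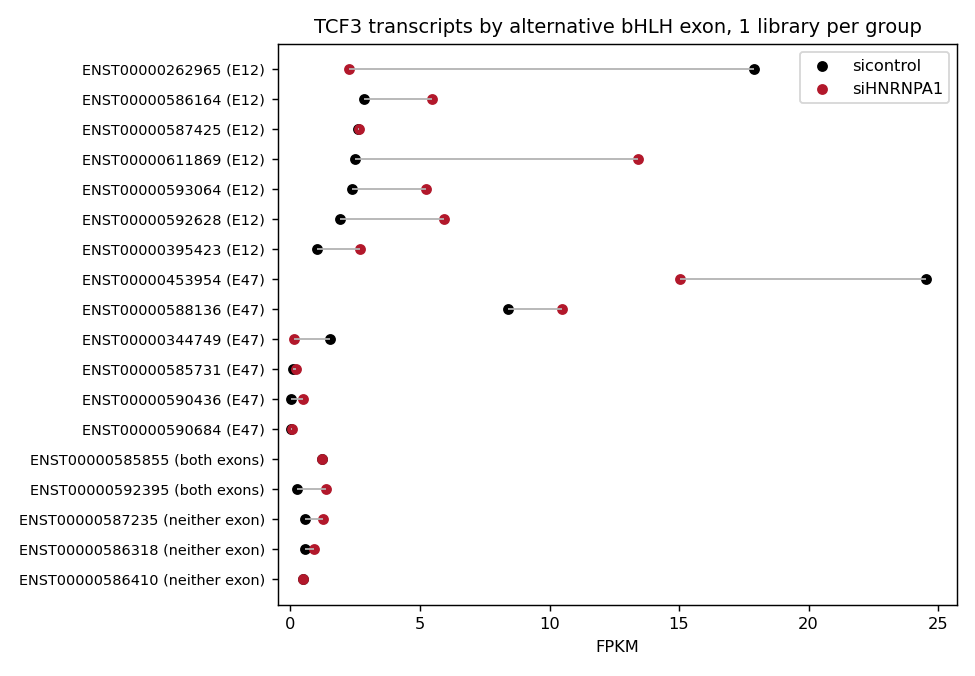
FPKM of each TCF3 transcript in the control library (black) and the siHNRNPA1 library (red), grouped by the alternative exon it carries, with 1 library per group. The E47 transcript ENST00000453954 makes up 21.7% of the gene in the siHNRNPA1 library and 35.7% in the control, and the E12 transcripts ENST00000262965 and ENST00000611869 lie in opposite orders.

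Transcript shares differed widely across the transcriptome. Of 5715 genes with at least 2 transcripts and 5 FPKM in both libraries, 2318 (40.6%) had a transcript whose share differed by at least 20 percentage points. Among the largest differences was that of IFITM1, an interferon-induced membrane protein, whose transcript ENST00000408968 made up 99.3% of the gene in the control and 0.313% in the siHNRNPA1 library. The chaperonin gene HSPD1 had 3.80% of ENST00000388968 in the control and 99.0% in the siHNRNPA1 library. LMNA, the gene of lamin A and C, had 97.4% and 2.52% of ENST00000368300. In TOP2B and DDX19A a transcript annotated as a substrate of nonsense-mediated decay made up 0.490% and 0.115% of the gene in the control and 96.2% and 93.9% in the siHNRNPA1 library. KIAA0368, MCM3AP, NREP, PAICS and ZBED5 completed the 10 largest differences, all of 93.3 points or more. HNRNPA1's own largest difference was 5.16 points. Of 24 literature HNRNPA1 splicing targets, 16 passed the expression minimum and 10 differed by at least 20 points. APP, the amyloid precursor gene, had the largest difference (58.1 points), followed by IRF3 (37.2), FGFR2 (33.8) and CDK2 (33.4). The median of the 16 genes was 22.6 points, at the 68.3rd percentile of random lists matched on expression and number of transcripts, inside the random range. In gene level these 24 targets, which include HNRNPA1 itself, had a median log2 fold of -0.84 (0.04th percentile, 0.01st with GC content and length matched), with 9 at least 2-fold lower and 1 higher. CASP2 (-2.10), APP (-2.04), HRAS (2.02) and CTNND1 (-1.92) had the largest folds, and HRAS stood at 0.97 after subtraction of the nearest genes. CTNND1 overlaps the readthrough gene TMX2-CTNND1 on the same strand. Because 1 library per group gives no measure of how stable such shares are, none of these differences can be set against replicate spread.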

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

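HNRNPA1 stayed lower in the siHNRNPA1 library under each alternative run for it. Its log2 fold was -2.03 after rescaling to a sum of 1000000, -1.72 after median ratio scaling and -1.73 from its leading transcript. The count of 2-fold lower genes was 947 with a pseudocount of 5 FPKM, 1450 at a mean FPKM of at least 5, 4088 at a 1.5-fold threshold and 1003 after subtraction of the nearest genes. The count of 2-fold higher genes was 841 with a pseudocount of 5 FPKM, 2887 at a 1.5-fold threshold and 962 after subtraction of the nearest genes. Another threshold or minimum sets its counts by construction. Genes with a transcript share difference numbered 1473 at 10 FPKM, 4278 at 1 FPKM and 1475 at 30 percentage points. The difference in the E47 share of TCF3 was -12.0 points with transcripts of at least 0.5 FPKM and -9.90 with protein-coding transcripts. Neither setting left out all E12 transcripts that begin within the gene, so neither shows how far the difference rests on them. The percentile of the transcript share differences of literature HNRNPA1 targets was 63.9 at 1 FPKM. Annotated terms beyond all random lists numbered 64 with expression matched and 24 with GC content and length matched as well. Among named genes past 2-fold and list medians outside the random range, ISG15 alone had the other sign under a setting, with -0.040 after subtraction of the nearest genes. The cause was not tested for HNRNPA1, the pseudocount, the target percentile and ISG15. The number of lists outside the random range lay between 9 and 14 in the settings in which it was counted, which leave out counts scaled to the library total and the 1.5-fold threshold. The matching on GC content and length was chosen after the data had been seen, and the other alternatives were planned. No paired analysis was possible because each group had 1 library. With 1 library per group no library could be left out, and depth limits chiefly the genes with few counts, such as HIST1H2BJ with 6 counts in the control library.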

Other observations

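Most histone genes with a HIST symbol were higher. Of 30 such genes with a mean FPKM of at least 1, a set chosen after the data were seen that includes the 7 measured genes of the fixed list, 25 were at least 2-fold higher in the siHNRNPA1 library and none was 2-fold lower, with a median log2 fold of 1.31. Equal capture of histone messages in both libraries was not tested. Of 13 mitochondrially encoded messages 1 was at least 2-fold lower and none 2-fold higher, with a median log2 fold of -0.43, against -0.13 for all genes.

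The test of fewer dividing cells and the matching on GC content and length were chosen after the values had been seen, as was the decision to leave the stress response list undecided. The bounds of the other tests were set before their results. The first pattern is the wide spread of folds, with 2609 genes at least 2-fold lower and 1480 at least 2-fold higher. A trend with GC content and transcript length may account for much of it, since rho with GC content was 0.58 and 67.7% of the genes past 2-fold were within 2-fold once the median of their nearest genes was subtracted. The standard deviation of the log2 folds was 1.01 before the subtraction and 0.759 after it. With 1 library per condition, nothing separates a trend from library preparation or RNA quality from one that follows the loss of HNRNPA1. HNRNPA1 itself stood at -1.87 after the subtraction.

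The second pattern is the shift of the cell cycle and stress lists. As the whole cause, the trend with GC content and length is argued against for the mitosis list, which stayed at the 0.06th percentile of lists matched on both. The same holds for the p53 target list, above 100% of such lists. This covers the fixed lists only. The KEGG cell cycle pathway (112 genes), below all expression-matched lists, lay at the 10.5th percentile with both matched, inside the random range. Oocyte meiosis (84 genes), also below all expression-matched lists, lay at the 2.45th percentile, just outside it. The p53 signaling pathway (56 genes) lay at the 60.35th. The mitosis median was -1.28 before the subtraction and -0.59 after it, so that part of that shift may still go with the trend. For the integrated stress response list nothing is decided, because its median was inside the random range before the matching and at the 89.1st percentile after it. Fewer dividing cells in the siHNRNPA1 library could also lower mitosis genes and stay open, as 15.4% of the members lay above 0 after the subtraction, between the bounds of 10% and 50% set for and against it, and an effect of the knockdown itself stays open too.

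The third pattern is the 40.6% of genes with a transcript share difference of at least 20 points. A trend towards shorter transcripts is argued against, since the transcript with the largest gain was shorter than that with the largest loss in 44.2% of these genes, and so is a general gain of transcripts subject to nonsense-mediated decay, whose summed share was higher in the siHNRNPA1 library in 44.4% of 2682 genes. Low depth is undecided, as the percentage of genes with a difference was 33.1% in the group with the most reads and 44.5% in that with the fewest, or 74.3% of it. Reads divided between near-identical transcripts may account for part of the pattern, because the percentage was 26.9% where the leading pair of transcripts shared least of their 31-nucleotide words and 49.9% where they shared most, a ratio of 1.86. Whether this touches the E47 share of TCF3 was not tested, and a difference in splicing after the knockdown stays open.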
